A study of Arabidopsis thaliana with 29 samples.

How the data were processed

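The scanner text files of all 29 arrays were read directly. Per the file headers the signals were extracted with Agilent Feature Extraction 10.7.3.1, and the processed signal is an intensity after background subtraction and multiplicative detrending. Per the labels' protocols RNA with an integrity number above 8.0 was used, and 0.5 µg was labelled with Cy3 for one-colour hybridisation. Per the same labels plants grew 10 days in vitro and 18 days on soil at 20 °C by day and 18 °C by night in 8-hour days, and then at 10 °C and 8 °C in 16-hour days. Rosettes at 3 weeks had reached stage 1.35 in Col-0 and 1.14 in the mutant, per the labels. Pooling of plants is not given in the sources used here.

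The authors deposited log2 values that, per the submitters' processing notes, were quantile normalized. The columns fell into a set of 23 and a set of 6 arrays by their medians (7.259 to 7.292 and 6.759 to 6.762), so they were tested only within the 23. The lowest correlation of a deposited column with the log2 scanner values of its array was 0.991. How the deposited values treated background and replicate spots is not given in the sources used here. No column was left unmatched.

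Values were log2 of the processed signal, less the 75th percentile of the array. Each array held 45220 spots, 43803 of them not controls, for 43603 probes, 50 of which were spotted 5 times and averaged. Of the probes 36136 had 1 locus, 452 several and 7015 none in the annotation of the array files, 34165 of them matched through a transcript accession. This gave 26455 loci, 7474 with more than 1 probe, and 10254 with a gene symbol. The probe with the highest mean signal stood for its locus; 4 of 115 comparisons between probes of named genes disagreed in sign. A locus was tested if well above background, per the scanner software, in at least 3 arrays of at least 1 group. That left 20412 genes, 8822 with a symbol and 284 with a missing value, and 1 locus was left out because a group had no value. Arrays of a group correlated at 0.9254 to 0.994. The first components held 33.3%, 20.6% and 17.7% of the variance, and the second correlated with array brightness at r = 0.749.

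Genes were tested with limma, with a mean per group over all 29 arrays, moderated variances and Benjamini-Hochberg adjustment within each of 13 comparisons, and called at an adjusted p under 0.05. The same tool gave the p-values of every gene named. Unadjusted p fell under 0.05 for 1337, 8421, 3694 and 5212 genes between genotypes at 20 °C and at the 3 times in the cold, and for 5411, 2049 and 3047 in the interactions. Arrays lay on 9 slides read on 2 days: the 20 °C arrays shared slides with 24 hours in part, and 1 week and 3 weeks had slides of their own. The median difference of all genes was -0.11 in Col-0 at 3 weeks, and no other scaling shifted such a median by more than 0.1 (largest shift 0.08).

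Gene lists were tested with camera, a competitive test of a list against all other genes, with a preset correlation between genes of 0.01 and adjustment over 25 lists per comparison. Of 325 tests 154 passed, and 3 held when the correlation was estimated from the data. Median, mean and test direction differed in sign in 27 of the 325, and in 0 of the 154. The lists cover CBF factors, cold-regulated genes, cold shock domain proteins, ribosomal proteins of both cytosolic subunits and of organelles, ribosome biogenesis, rRNA processing, translation factors, the proteasome, anthocyanins, salicylic acid defence, jasmonate, the clock, floral transition, photosynthesis, starch and sugar, glucosinolates, heat shock and senescence. Markers of dividing cells, floral organs, roots, guard cells and trichomes stand for other cell types a rosette sample could hold. Of 311 explicit entries 15 were left out because their annotation held none of the names listed. The pattern for the large subunit also matched 6 disease resistance loci named RPP, which were removed before values were seen; kept, 9 of 9 list calls were the same.

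Comparisons, lists, the rule for naming genes and most alternatives were fixed before the data were examined. REIL1 and REIL2 were always named. For each genotype and Col-0 cold comparison the candidates were the 5 genes per direction with the largest change among those called, with a symbol and with groups that did not overlap, and called members of lists. For interactions they were the 4 largest per direction, and for the mutant the genes named in Col-0. Of these candidates the text prints a part, mostly those whose call held in every leave-out, chosen after values were seen. Groups without overlap also give the same sign on every slide. Where these traits are reported for genes chosen by them, they follow from the choice and are no further support. The genes listed as changed at all 4 times are outside that rule.

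In a self-test on simulated arrays with the spread of the real genes, 100 genes were shifted at each size of change. At log2 changes of 1 and 2 the method recovered 57% and 94% for genotype at 20 °C (12 false calls), 37% and 83% at 24 hours (5 false calls), 43% and 91% for Col-0 at 1 week (3 false calls), and 14% and 62% for the 3-week interaction (5 false calls). With ribosome biogenesis factors shifted by 0.5 in the 20 °C genotype comparison, 1 of 25 lists passed. These simulated genes varied independently, with no slide or brightness effect. The self-test therefore cannot show how often lists of correlated genes, or arrays that differ in brightness, give false calls.

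Whether replicate numbers pair the samples was checked by correlating residuals of arrays with the same number. Every pair exceeded 0.1 for the genotypes at 1 week (r from 0.29 to 0.77, best with the own number in 2 of 3 pairs, which also share a slide) and in no other comparison. Alternatives covered scaling, background correction, filters, probes, variance model, slide and replicate blocks, leaving out arrays, thresholds and estimated correlations. Random splits used all regroupings or 100 drawn at random, and the noise simulation 100 draws. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1, statmod 1.5.0 and the data.table package, version 1.17.8). No array was left out.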

Results

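Transcript levels were measured in mature rosette leaves of Arabidopsis thaliana on 29 one-colour Agilent arrays. The wild type Col-0 was set beside the double mutant reil1-1 reil2-1, which carries insertions in REIL1 and REIL2, homologs of the yeast ribosome biogenesis factor REI1. Plants were sampled at 20 °C (6 Col-0 and 5 mutant arrays) and, with 3 arrays per genotype and time, after 24 hours, 1 week or 3 weeks at 10 °C. Days were lengthened from 8 to 16 hours at the shift and plants grew older, so every difference from 20 °C also spans day length and age. Between 60.8% and 75.6% of spots per array were well above background. Among these spots alone the log2 of the median signal over background lay between 3.83 and 5.57. No spot on any array was saturated. After filtering, 20412 genes were tested. Levels are log2 signals relative to the 75th percentile of their array, ± SD over arrays for groups and ± SE for differences. The labels do not state that the arrays of a group came from separate plants, so p-values measure the spread between these samples, which may be technical.

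The transcripts of both mutated genes were far lower in the mutant than in Col-0. In Col-0, REIL1 (AT4G31420) stood at 0.88 ± 0.12 (n = 6) at 20 °C, and at 0.72 ± 0.31, 1.16 ± 0.64 and 1.10 ± 0.80 (n = 3 each) at 24 hours, 1 week and 3 weeks in the cold. In the mutant it stood at -3.92 ± 0.51 (n = 5), -4.23 ± 0.51, -4.23 ± 1.10 and -4.92 ± 1.17 (n = 3 each). REIL2 (AT2G24500) in Col-0 had 0.53 ± 0.33, 1.15 ± 0.30, 0.95 ± 0.39 and 0.26 ± 0.20 at the same times. In the mutant REIL2 had -4.06 ± 0.51, -4.17 ± 0.53 and -3.59 ± 0.52 up to 1 week, and -1.57 ± 1.10 at 3 weeks, where its 3 arrays ranged from -2.65 to -0.45. The difference between genotypes in REIL1 was -4.79 ± 0.38 at 20 °C (adjusted p = 1.21e-08), -4.95 ± 0.51 at 24 hours (adjusted p = 2.02e-06), -5.39 ± 0.51 at 1 week (adjusted p = 4.77e-07) and -6.02 ± 0.51 at 3 weeks (adjusted p = 6.9e-08). For REIL2 it was -4.59 ± 0.31 at 20 °C (adjusted p = 4.54e-10), -5.32 ± 0.41 at 24 hours (adjusted p = 1.11e-08), -4.54 ± 0.41 at 1 week (adjusted p = 2.18e-07) and -1.84 ± 0.41 at 3 weeks (adjusted p = 0.00644), where leaving out mutant replicate 3 gave an adjusted p of 0.0686. At every time all mutant arrays lay below all Col-0 arrays for both genes. Both probes of REIL1 gave this result and REIL2 had 1 probe. Where the probes lie relative to the insertions was not analysed here. In Col-0 neither gene passed the test against 20 °C, with REIL2 differing by 0.61 ± 0.36 at 24 hours (adjusted p = 0.155).

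**Figure D1:**
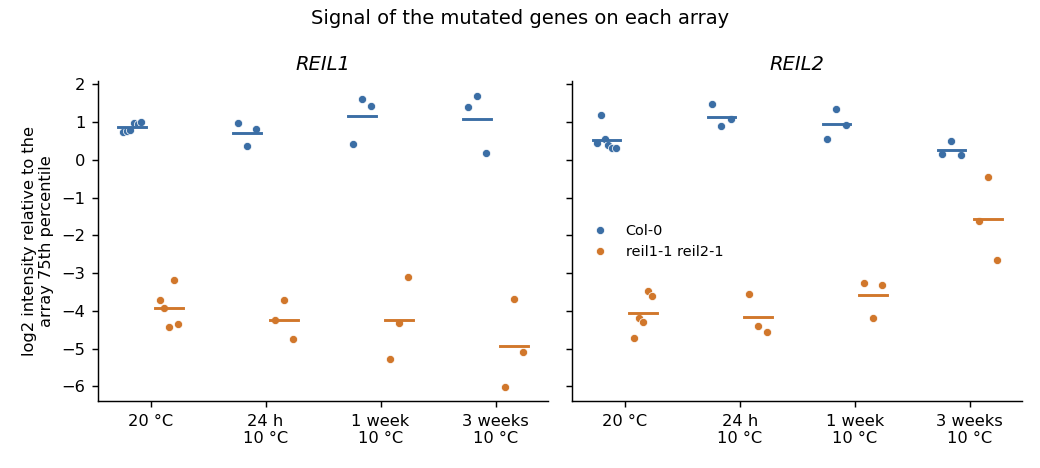
Level of REIL1 and REIL2 in each array (points) with group means (short lines), as log2 signal relative to the 75th percentile of the array, for Col-0 and the mutant at 20 °C and 24 hours, 1 week and 3 weeks in the cold. All mutant arrays lie below all Col-0 arrays, and REIL2 in the mutant at 3 weeks (-1.57 ± 1.10) lies nearest to Col-0 (0.26 ± 0.20).

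Arrays also differed in brightness in a way that followed the groups in part. The log2 75th percentile of the signal averaged 9.76 in Col-0 and 9.61 in the mutant at 20 °C, 9.42 and 10.56 at 24 hours, 10.01 and 10.48 at 1 week, and 10.21 and 10.84 at 3 weeks. Col-0 replicates 2 and 3 at 24 hours were the dimmest of all 29 arrays by median signal (53.3 and 53.7, against 150.2 for replicate 1), and their small-subunit ribosomal protein medians, relative to Col-0 at 20 °C, were 1.88 and 2.04 against 0.62.

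**Figure D2:**
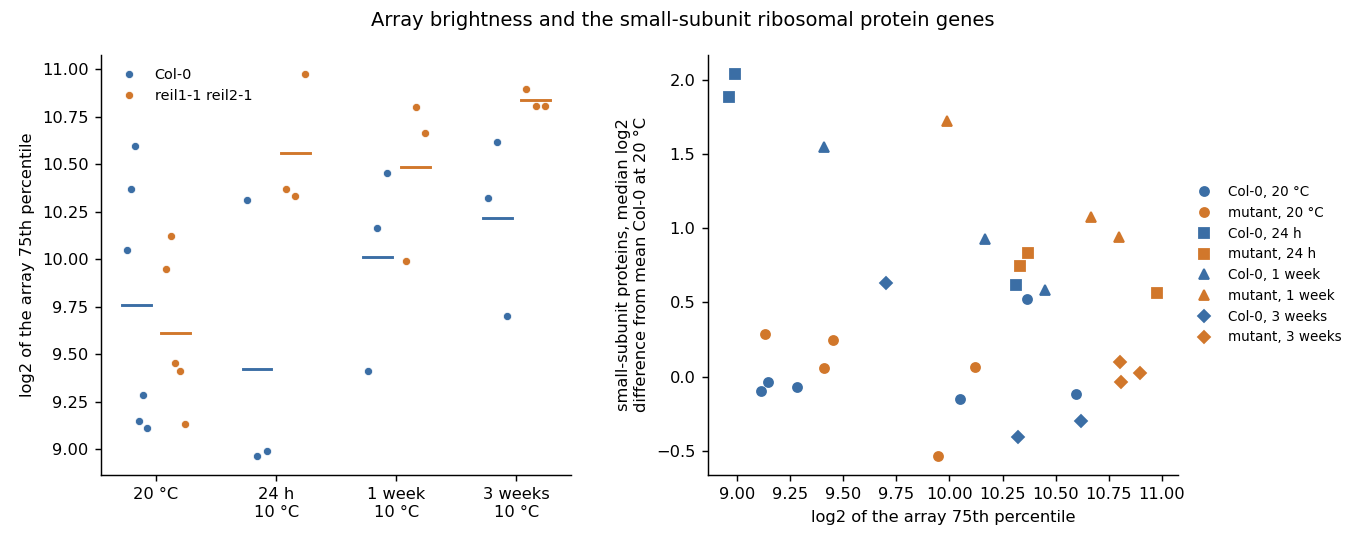
Left, log2 of the 75th percentile of the spot signals of each array (points) by group; right, the median log2 level of small-subunit ribosomal protein genes in each array against that percentile. Col-0 replicates 2 and 3 at 24 hours lie lowest on the left, at 8.97 and 8.99, against 10.31 for replicate 1 of that group.

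At 20 °C the comparison asked what the mutations change before any cold. MRD1 (AT1G53480) rose from -4.54 ± 0.69 in Col-0 (n = 6) to -0.25 ± 0.58 in the mutant (n = 5), a difference of 4.29 ± 0.60 (adjusted p = 0.000161). TIF3C2 (AT3G22860), annotated as a translation initiation factor, rose by 3.75 ± 0.43 (adjusted p = 7.98e-06), the MADS-box gene AGL19 by 2.80 ± 0.33 (adjusted p = 1.01e-05), and the helix-loop-helix genes BHLH100 and BHLH101 by 3.73 ± 0.73 and 3.09 ± 0.53 (adjusted p = 0.00906 and 0.00207). Lower in the mutant were CYP78A8, with a difference of -2.59 ± 0.43 (adjusted p = 0.00127), the phosphatidylinositol transporter gene COW1, with -2.53 ± 0.38 (adjusted p = 0.00036), and the superoxide dismutase gene CSD2, with -2.04 ± 0.32 (adjusted p = 0.000837). For each of these 8 genes every mutant array lay on the same side of every Col-0 array, all 5 slides that held both genotypes gave the same sign, and the call held whichever array was left out. These are no separate checks, since the genes were chosen for groups without overlap and mostly for calls that held. In Col-0, TIF3C2, BHLH100 and BHLH101 were well above background in 1, 2 and 1 of 6 arrays, so the size of their difference is uncertain. The floral repressor FLC was not well above background in any mutant array and was at least 7.1-fold lower than in Col-0 (adjusted p = 0.0035, same sign on 5 of 5 slides, although single arrays of the groups overlapped). Such bounds raise each array of the dim group to at least the lowest value of any probe well above background on that array.

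In all, 180 genes differed at 20 °C, 126 higher and 54 lower in the mutant, and 137 with slide as a block. Leaving out mutant replicate 4 or 5 gave 105 or 97. The share higher in the mutant, 70%, was 53.1% with only the 20 °C arrays on slides shared with 24 hours and 80.3% with only the others. Cold-regulated genes stood higher without cold: 28 of 30 measured members had positive differences (median 0.39, adjusted p = 3.95e-09 by camera), and 2 passed singly over all genes, 4 adjusted over the list alone. Among them, galactinol synthase gene GolS2 rose by 1.68 ± 0.24 (adjusted p = 0.000161). The list's median was positive on 5 of 5 slides, from 0.04 to 0.62, with an adjusted p = 0.117 with an estimated correlation. Anthocyanin and flavonoid genes leaned the same way (20 of 22 positive, median 0.42, adjusted p = 2.49e-05), with no single call over all genes by limma, none adjusted over the list alone, and the same sign on 3 of 5 slides. That list had adjusted p = 0.507 with an estimated correlation. The 3 measured trichome markers were lower (median -1.003, adjusted p = 0.00328, 0 called over all genes, 2 adjusted over the list alone, same sign on 5 of 5 slides). The list reached adjusted p = 0.0855 with an estimated correlation. The 8 guard cell markers were higher (median 0.38, adjusted p = 0.0227, 0 called either way, same sign on 5 of 5 slides). The camera test gave adjusted p = 0.564 with an estimated correlation. The 4 CBF genes (median 0.84), 18 clock genes (0.25), 15 starch and sugar genes (0.15) and 4 floral organ markers (-0.89, 2 lower adjusted over the list alone) each reached an adjusted p of 0.0497, with 0 calls over all genes. With an estimated correlation their adjusted p was 0.747, 0.747, 0.764 and 0.337. Under normexp the floral organ median was -0.31 and the trichome median -0.55. Col-0 replicate 2 stood apart in the direction of the call for clock genes (-0.29, others 0.05 to 0.15) and for starch and sugar genes (-0.76, others -0.09 to 0.32).

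Ribosomal protein lists did not pass at 20 °C, where single arrays stood apart. Large-subunit cytosolic ribosomal protein genes had 1 call among 122 (median 0.08, adjusted p = 0.104). The 76 small-subunit genes had a median of 0.04 (adjusted p = 0.429), which became -0.002 under quantile normalization. Slide medians ran from -0.42 to 0.46 in the large subunit and from -0.44 to 0.37 in the small, with 3 of 5 positive in each. Col-0 replicate 2 had array medians of 0.57 and 0.52 for these lists, against -0.17 to -0.06 and -0.15 to -0.04 in the other Col-0 arrays. Mutant replicate 1 had -0.54 and -0.53, against 0.13 to 0.37 and 0.06 to 0.29 in the other mutant arrays, so the lists differed in sign between the remaining arrays of the genotypes. Among 39 ribosome biogenesis factors the nucleolin gene NUC-L2 rose by 2.67 ± 0.42 (adjusted p = 0.000673, every mutant array above every Col-0 array), and the list did not move (median -0.03, mean 0.04, adjusted p = 0.994). Translation factors had 2 calls among 86 (median -0.02, mean and test upward, adjusted p = 0.901). Other lists that did not pass were the proteasome (adjusted p = 0.173), salicylic acid defence (0.321), jasmonate (0.587), cold shock domain proteins (0.468), heat shock (0.321), senescence (0.474), root markers (0.587, 1 higher adjusted over the list alone), glucosinolate biosynthesis (0.113), floral transition (0.527, FLC called), plastid and mitochondrial ribosomal proteins (0.441) and rRNA processing (0.901). Photosynthesis genes (median 0.12, adjusted p = 0.232) and dividing-cell markers (median 0.01, mean -0.03, adjusted p = 0.859) did not pass either, and their medians changed sign under another scaling.

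**Figure D3:**
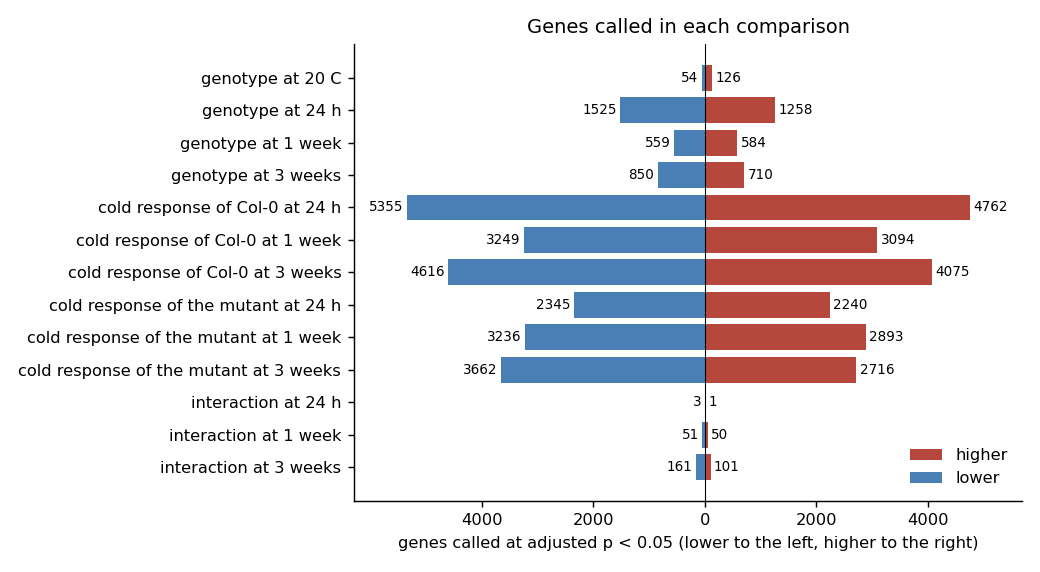
Number of genes past an adjusted p of 0.05, higher (up) and lower (down), for each of the 13 comparisons, out of 20412 genes tested. The genotypes differed in 180 genes at 20 °C and in 2783, 1143 and 1560 genes at 24 hours, 1 week and 3 weeks, and the genotype difference in the cold response passed for 4, 101 and 262 genes.

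After 24 hours in the cold the genotypes were compared to see how the early response differed. RPL3B (AT1G61580), a gene for large-subunit protein L3, stood at 0.14 ± 0.09 in the mutant and 1.90 ± 0.12 in Col-0 (n = 3 each), a difference of -1.76 ± 0.18 (adjusted p = 1.93e-06). TIF3C2 was higher by 3.70 ± 0.58 (adjusted p = 0.000656), and CYP78A8 differed by -3.35 ± 0.57 (adjusted p = 0.00169). These 3 genes had the same sign on 3 of 3 slides, held their call whichever array was left out, and also passed without both dim Col-0 arrays (adjusted p = 0.00407, 0.00407 and 0.0288). The alcohol-forming fatty acyl-CoA reductase gene CER4 was higher by 4.03 ± 0.74 (adjusted p = 0.00312) and the trichome gene TRY differed by -3.28 ± 0.52 (adjusted p = 0.000656), on 3 of 3 slides each, but without both dim arrays their adjusted p was 0.395 and 0.636. TIF3C2 and CER4 were well above background in 1 of 3 Col-0 arrays, which leaves the size of their difference uncertain. BHLH100, not well above background in Col-0, was at least 14.1-fold higher in the mutant (adjusted p = 0.00473, 3 of 3 slides, 0.358 without both dim arrays).

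The 24-hour count of 2783 genes (1258 higher, 1525 lower) depended on single arrays. It was 40 without both dim Col-0 arrays (29 higher, 11 lower), 188 with brightness as a covariate (136 higher, 52 lower) and 46 when only the groups compared were fitted (31 higher, 15 lower), so the balance of directions turned. These compare with 29, 60 and 52 with a single mutant array. The count was 975 with slide as a block, 1641 under quantile normalization, 11058 without Col-0 replicate 1, 190 (112 higher) and 212 (120 higher) without Col-0 replicate 2 or 3, and 435, 438 and 233 without mutant replicate 1, 2 or 3. Small-subunit ribosomal protein genes were lower in 74 of 76 members (median -0.75, adjusted p = 7.07e-10), with 6 calls over all genes and 0 adjusted over the list alone. The median was 0.07 without both dim arrays and 0.05 with brightness as a covariate, and ran from -1.30 to 0.19 across slides. For these genes adjusted p = 0.657 with an estimated correlation was found. The 122 large-subunit genes (9 lower, 1 higher, 2 lower adjusted over the list alone, median -0.71, adjusted p = 7.07e-10) moved alike, to 0.03 without both dim arrays. This became adjusted p = 0.657 with an estimated correlation. Of 30 cold-regulated genes 8 were lower and 1 higher (10 and 1 adjusted over the list alone, median -0.81, adjusted p = 0.00145), on 3 of 3 slides, from -1.24 to -0.24. This list had adjusted p = 0.657 with an estimated correlation, and its median was -0.21 under quantile normalization, -0.27 without both dim arrays and -0.08 with brightness as a covariate. The 4 CBF genes (median -1.81, adjusted p = 0.0376) included 2 calls, CBF1 at -1.82 ± 0.54 (adjusted p = 0.0367) and CBF2 at -1.79 ± 0.50 (adjusted p = 0.0312), which held in 1 of 6 leave-outs, without Col-0 replicate 1, and were -0.49 and -0.48 without both dim arrays. Plastid and mitochondrial ribosomal proteins (9 of 21 lower, 14 adjusted over the list alone, median -0.94, adjusted p = 0.000127) and photosynthesis genes (2 of 22 lower, 8 adjusted over the list alone, median -0.88, adjusted p = 0.000127) had the same sign on 2 of 3 slides, and the photosynthesis median was 0.06 under quantile normalization. Jasmonate genes (3 of 15 lower, median -0.65, adjusted p = 0.0472), guard cell markers (2 of 8 higher, 3 adjusted over the list alone, median 0.97, adjusted p = 0.0125) and dividing-cell markers (1 of 13 higher, 3 adjusted over the list alone, median 0.86, adjusted p = 0.0376) kept their sign on 3 of 3 slides. With brightness as a covariate the dividing-cell direction reversed (median -0.22, adjusted p = 0.406) and the guard cell median was 0.53. Without both dim arrays these medians were 0.28 and 1.13. With an estimated correlation each of the 9 lists had an adjusted p of 0.657 to 0.66. Ribosome biogenesis factors did not pass (1 higher and 1 lower of 39, adjusted p = 0.89), and their median of 0.11 turned to -0.29 without both dim arrays and -0.62 with brightness as a covariate. That of rRNA processing genes, which did not pass either (adjusted p = 0.0774), went from 0.63 to -0.17 and -0.74.

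At 1 week the question was whether acclimating leaves differed. NUC-L2 stood at -1.06 ± 0.94 in the mutant and -5.15 ± 0.96 in Col-0 (n = 3 each), a difference of 4.09 ± 0.56 (adjusted p = 6.22e-05). The anthocyanin regulator MYB90 was higher by 4.60 ± 0.98 (adjusted p = 0.0057) and MRD1 by 4.26 ± 0.81 (adjusted p = 0.00221). GMI1, not well above background in Col-0, was at least 12.6-fold higher (adjusted p = 2.4e-05). The flowering signal gene FT, not well above background in the mutant, was at least 24.8-fold lower there (adjusted p = 0.000537). GER3 differed by -5.05 ± 0.75 (adjusted p = 0.000165), CYP78A8 by -4.95 ± 0.57 (adjusted p = 9.01e-06) and GASA6 by -4.78 ± 0.77 (adjusted p = 0.000462). MYB90 was well above background in 1 of 3 Col-0 arrays and CYP78A8 in 1 of 3 mutant arrays, so these sizes are uncertain. For these 8 genes the groups did not overlap, 3 of 3 slides gave the same sign, and every leave-out kept the call.

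Of 1143 genes called at 1 week 584 were higher and 559 lower. The counts were 749 with replicate number as a block and 752 with slide as a block, and 541, 709, 637 and 510 without Col-0 replicate 1, Col-0 replicate 2, mutant replicate 2 or mutant replicate 3. Ribosome biogenesis factors were higher in 38 of 39 members (median 0.85, adjusted p = 3.48e-16), 11 called over all genes and 20 adjusted over the list alone, with slide medians from 0.72 to 0.95. The same members gave adjusted p = 0.168 with an estimated correlation. Besides NUC-L2 they included NAP57, higher by 1.76 ± 0.36 (adjusted p = 0.00431). Genes annotated to rRNA processing (3 of 12 higher, 7 adjusted over the list alone, median 1.04, adjusted p = 0.000372) included AT3G22660, higher by 1.46 ± 0.29 (adjusted p = 0.00332). Their joint test had adjusted p = 0.697 with an estimated correlation. Translation factors (7 higher and 1 lower of 86 either way, median 0.29, adjusted p = 5.82e-05, 3 of 3 slides) included TIF3C2, higher by 4.06 ± 0.58 (adjusted p = 0.000109), and the eIF4A-like AT1G51380, higher by 2.53 ± 0.43 (adjusted p = 0.000673). That list had adjusted p = 0.168 with an estimated correlation. Ribosomal protein genes had 8 higher and 1 lower of 122 in the large subunit (median 0.19) and 5 higher of 76 in the small (median 0.20), the same counts adjusted over either list alone, both at an adjusted p of 0.000372 and the same sign on 2 of 3 slides. The adjusted p was 0.774 for both with an estimated correlation. Brightness as a covariate gave medians of 0.55 and 0.56 for the ribosomal lists and 0.58 for biogenesis factors, and quantile normalization gave 0.40 for the large subunit. The single large-subunit call downward was RPL3B, at -1.04 ± 0.18 (adjusted p = 0.000932), and the small-subunit gene AT5G59240 was higher by 1.41 ± 0.29 (adjusted p = 0.0037).

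Metabolic and defence groups differed as well at 1 week. Anthocyanin and flavonoid genes were higher in 21 of 22 members (median 1.15, adjusted p = 1.51e-08), 7 called higher and 1 lower over all genes, 12 and 1 adjusted over the list alone, on 3 of 3 slides. The list reached adjusted p = 0.198 with an estimated correlation. Starch and sugar genes (4 of 15 higher, median 0.39, adjusted p = 0.00163) included the glucose-phosphate translocator gene GPT2, higher by 3.89 ± 0.80 (adjusted p = 0.00423), and GBSS1, higher by 2.09 ± 0.35 (adjusted p = 0.000619). The camera test gave adjusted p = 0.697 with an estimated correlation. The starch and sugar median was 0.02 with brightness as a covariate. Glucosinolate genes were higher (1 of 16, 3 adjusted over the list alone, median 0.66, adjusted p = 0.000608). For these genes adjusted p = 0.697 with an estimated correlation was found. All 22 photosynthesis genes had negative differences (median -0.45, adjusted p = 0.00163), and the 1 call was LHCB4.3, at -2.44 ± 0.37 (adjusted p = 0.000199). The photosynthesis median nearly vanished in other settings, at -0.03 under quantile normalization, -0.02 under normexp and -0.01 with brightness as a covariate. This became adjusted p = 0.774 with an estimated correlation. Salicylic acid defence genes were lower as a list (19 of 22 negative, median -1.17, adjusted p = 0.00195, 3 of 3 slides) with 0 single calls by limma. The same members gave adjusted p = 0.774 with an estimated correlation. Plastid and mitochondrial ribosomal proteins (2 of 21 lower, 5 adjusted over the list alone, median -0.69, adjusted p = 0.00734) and floral organ markers (2 of 4 lower, median -1.71, adjusted p = 0.0159) were lower. The organellar median was -0.18 with brightness as a covariate and -0.43 under normexp, the floral organ median -0.79 under normexp, and the glucosinolate median 0.39 with the covariate. With an estimated correlation the floral organ list had an adjusted p = 0.198 and the organellar list did not pass. The senescence-associated sugar transporter gene SAG29 was higher by 3.42 ± 0.69 (adjusted p = 0.00372).

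**Figure D4:**
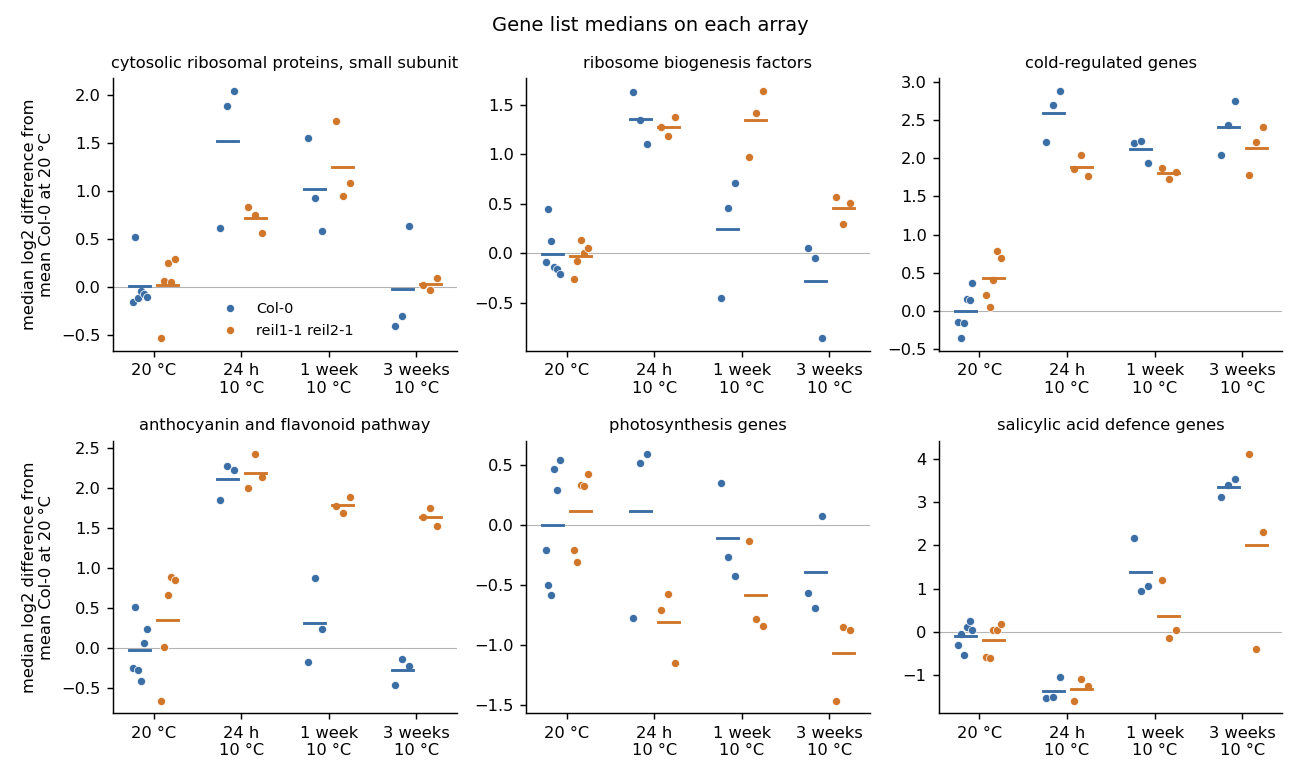
Median log2 level of 6 gene lists in each array (points) by group, relative to the mean over arrays of Col-0 at 20 °C. In the mutant at 3 weeks anthocyanin genes lie above Col-0 (median difference 1.72) and photosynthesis genes below (-0.65, but -0.09 under quantile normalization), while salicylic acid defence genes spread widely.

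At 3 weeks the comparison addressed acclimated leaves. Rosettes were then at stage 1.35 in Col-0 and 1.14 in the mutant, so genotype and rosette stage cannot be told apart at this time. The helix-loop-helix gene bHLH39 was higher by 6.10 ± 0.96 (adjusted p = 0.000222), BHLH100 by 5.18 ± 0.99 (adjusted p = 0.00154), and the Nudix hydrolase gene NUDT24 rose from -6.34 ± 0.83 in Col-0 to -0.78 ± 0.80 in the mutant (n = 3 each), by 5.56 ± 0.68 (adjusted p = 1.15e-05). Of these, bHLH39 was well above background in 1 of 3 Col-0 arrays, and the size of its difference is uncertain. The flavonol regulator MYB11, not well above background in Col-0, was at least 9.32-fold higher (adjusted p = 5.87e-07). GER3 differed by -7.34 ± 0.75 (adjusted p = 8.32e-07) and the defensin gene PDF1.2 by -6.31 ± 0.95 (adjusted p = 0.000138). Not well above background in the mutant were MSRB6, a methionine sulfoxide reductase gene, RL5 and FT, at least 63.3-fold, 23.7-fold and 14.8-fold lower than in Col-0 (adjusted p = 5.45e-08, 7.81e-07 and 0.000932). For each of these genes the groups did not overlap, 3 of 3 slides gave the same sign, and every leave-out kept the call. Again these traits follow from how the genes were chosen.

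At this time 1560 genes were called, 710 higher and 850 lower, and 1120 with slide as a block; the count was 651 without Col-0 replicate 3 and 849 without mutant replicate 3. Anthocyanin and flavonoid genes were higher in 21 of 22 members (median 1.72, adjusted p = 9.65e-13), 12 called over all genes and 19 adjusted over the list alone, with slide medians from 1.63 to 1.96. Their joint test had adjusted p = 0.146 with an estimated correlation. Ribosome biogenesis factors were higher in 38 of 39 (median 0.68, adjusted p = 2.66e-07), 4 called either way, among them NUC-L2 by 2.94 ± 0.56 (adjusted p = 0.00161). That list had adjusted p = 0.325 with an estimated correlation. All 12 rRNA processing genes had positive differences (1 called, median 0.94, adjusted p = 0.000447). The list reached adjusted p = 0.561 with an estimated correlation. With brightness as a covariate the biogenesis median was 0.34 and that of rRNA processing 0.28. Translation factors (5 of 86 higher, 4 adjusted over the list alone, median 0.43, adjusted p = 0.000174) included TIF3C2, by 4.76 ± 0.58 (adjusted p = 1.12e-05). The camera test gave adjusted p = 0.146 with an estimated correlation. Ribosomal protein genes had 10 higher and 1 lower of 122 in the large subunit (11 and 1 adjusted over the list alone, median 0.12, adjusted p = 0.0192) and 3 higher of 76 in the small (1 adjusted over the list alone, median 0.08, adjusted p = 0.0376), on 2 of 3 slides. Slide medians ran from -0.518 to 0.435 in the large subunit and from -0.513 to 0.406 in the small. The adjusted p was 0.753 for both lists with an estimated correlation.

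Starch and sugar genes at 3 weeks (5 of 15 higher, 10 adjusted over the list alone, median 1.19, adjusted p = 6.69e-06, 3 of 3 slides) included the ADP-glucose pyrophosphorylase gene APL3, higher by 2.22 ± 0.40 (adjusted p = 0.000941). For these genes adjusted p = 0.298 with an estimated correlation was found. Brightness as a covariate gave medians of 0.54 for starch and sugar genes, 0.30 for dividing-cell markers and -0.26 for floral transition genes. Dividing-cell markers were higher (1 of 13, 3 adjusted over the list alone, median 1.01, adjusted p = 0.000932, 2 of 3 slides). This became adjusted p = 0.561 with an estimated correlation. Photosynthesis genes were lower (2 of 22 called, median -0.65, adjusted p = 0.000207, 3 of 3 slides), LHCB4.3 at -2.04 ± 0.37 (adjusted p = 0.000918). The list median was -0.09 under quantile normalization, -0.05 under normexp and -0.13 with brightness as a covariate. The same members gave adjusted p = 0.579 with an estimated correlation. Floral transition genes were lower (5 of 14, 7 adjusted over the list alone, median -0.73, adjusted p = 0.00144, 3 of 3 slides), FLC at -3.77 ± 0.86 (adjusted p = 0.0074, 0.184 under normexp). Their joint test had adjusted p = 0.298 with an estimated correlation. Glucosinolate genes, higher as a list at 1 week, were lower (2 of 16, 4 adjusted over the list alone, median -0.56, adjusted p = 0.00166), BCAT4 at -1.88 ± 0.31 (adjusted p = 0.000343) and BAT5 at -1.33 ± 0.27 (adjusted p = 0.00263). That list had adjusted p = 0.579 with an estimated correlation. Salicylic acid defence genes (1 of 22 lower, median -1.34, adjusted p = 0.00138) and senescence genes (3 of 8 lower, median -1.25, adjusted p = 0.00383) had the same sign on 2 of 3 slides, the defence list ranging from -3.97 to 0.86. With an estimated correlation the adjusted p was 0.579 and 0.298. Brightness as a covariate gave medians of -0.77 for senescence genes, -0.88 for glucosinolate genes and 0.19 for translation factors. Plastid and mitochondrial ribosomal proteins were lower (20 of 21 negative, 0 called by limma, median -0.47, adjusted p = 0.00881). The list reached adjusted p = 0.606 with an estimated correlation. The median was 0.01 with brightness as a covariate.

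Between times, 56 genes differed in the same direction in all 4 genotype comparisons, 36 higher and 20 lower. Both mutated genes were among the lower, and MRD1, TIF3C2, AGL19, NUC-L2 and GMI1 among the higher. Loci without a symbol had larger differences at 20 °C than REIL1 (-4.79). They were AT2G36970 (-7.78), AT3G12760 (-7.49), AT4G16215 (6.14), AT4G29200 (5.18), AT5G03090 (5.09) and AT4G07408 (-4.93). Of these only AT4G29200 lay within 500 annotated loci of a mutated gene. The calls at 1 week and 3 weeks shared 489 genes with the same sign (independent lists: 20.3 up and 23.3 down) and 3 with opposite sign. The 24-hour calls shared 192 genes of the same sign and 52 of opposite sign with 1 week, and 332 and 22 with 3 weeks. The calls at 20 °C shared 99, 90 and 110 of the same sign with the later times, and 2, 0 and 0 of opposite sign. Across genes, which are not independent replicates, the 1-week genotype effect of 1 slide correlated with that of the other slides at r = 0.671, against 0.089 at 24 hours and 0.205 at 3 weeks. At 24 hours the single slide held the bright Col-0 array and the other slides the dim ones, so brightness parts them. At 20 °C, where 2 slides shared with 24 hours were set against 3 others, r was 0.188.

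The cold response of Col-0 after 24 hours served as the reference. The dehydrin gene LTI30 rose by 7.48 ± 0.41 (adjusted p = 5.99e-12), the kinase gene CIPK25 by 6.32 ± 0.31 (adjusted p = 1.04e-12) and the clock-related RVE2 by 5.91 ± 0.36 (adjusted p = 2.43e-11). AZI1, not well above background at 20 °C, rose at least 91.9-fold (adjusted p = 3.61e-10). The expansin gene EXPA8 fell by 7.002 ± 0.51 (adjusted p = 3e-10), GASA6 fell by 6.23 ± 0.67 (adjusted p = 1.09e-07) and BXL1 fell by 6.21 ± 0.44 (adjusted p = 2.28e-10), while SEN1 fell at least 44.6-fold to below background (adjusted p = 6.43e-09). BXL1 was well above background in 1 of 3 cold arrays. All 3 cold arrays lay outside the range of the 6 arrays at 20 °C for each, which the choice of genes required, and every leave-out kept the call.

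In all 10117 genes were called, 4762 up and 5355 down. The count was 8511 with slide as a block, 6528 and 6725 without Col-0 replicate 2 or 3 at 24 hours, and 3047 without both. Of 30 cold-regulated genes 24 rose, over all genes and adjusted over the list alone (median 2.88, adjusted p = 7.03e-16), COR27 by 5.72 ± 0.65 (adjusted p = 2.56e-07), with slide medians from 2.56 to 3.30. This was 1 of 3 camera calls, all of this list in Col-0, that held with an estimated correlation (adjusted p = 0.0314, 0.0173 at 1 week and 0.0241 at 3 weeks). CBF1 rose by 4.75 ± 0.47 (adjusted p = 2.82e-08) and CBF2 by 4.60 ± 0.44 (adjusted p = 1.66e-08), among 3 of 4 CBF genes (median 3.92, adjusted p = 0.00324, 0.281 with an estimated correlation). Ribosomal protein genes rose almost throughout, 115 up and 1 down of 122 in the large subunit (116 and 1 adjusted over the list alone, median 1.52, adjusted p = 3.52e-24) and 74 of 76 in the small (median 1.54, adjusted p = 6.73e-21), with slide medians from 0.82 to 2.13. Their medians were 0.68 and 0.62 without both dim arrays, 1.07 and 1.12 under quantile normalization and 0.94 and 0.97 with brightness as a covariate. Their adjusted p was 0.281 and 0.302 with an estimated correlation. Biogenesis factors (27 of 39 up, 29 adjusted over the list alone, median 1.44, adjusted p = 7.53e-10) included the fibrillarin gene FIB2, by 3.81 ± 0.38 (adjusted p = 3.79e-08), and GAR1, by 2.67 ± 0.35 (adjusted p = 1.69e-06). The camera test gave adjusted p = 0.281 with an estimated correlation. Anthocyanin genes (16 up and 1 down of 22, 17 and 1 adjusted over the list alone, median 2.23, adjusted p = 5.49e-06) included F3H, by 3.28 ± 0.26 (adjusted p = 1.18e-09). For these genes adjusted p = 0.281 with an estimated correlation was found. Translation factors (39 up, 12 down of 86, adjusted p = 0.00299), plastid and mitochondrial ribosomal proteins (9 up, 2 down of 21, adjusted p = 0.0195, median 0.62, and -0.42 without both dim arrays), the proteasome (12 of 23 up, adjusted p = 0.021) and clock genes (10 up, 2 down of 18, adjusted p = 0.0216) passed upward. Salicylic acid defence genes (1 up, 10 down of 22, median -1.41, adjusted p = 0.0143), WRKY70 at -3.44 ± 0.55 (adjusted p = 2.4e-05), and heat shock genes (1 up, 7 down of 13, median -1.59, adjusted p = 0.0195), HSP90.1 at -3.80 ± 0.54 (adjusted p = 5.53e-06), passed downward. None of these lists passed with an estimated correlation.

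At 1 week in Col-0, COR27 rose by 7.27 ± 0.65 (adjusted p = 3.28e-08), CIPK25 by 6.70 ± 0.31 (adjusted p = 5.43e-13) and the kinase gene WNK9 by 6.15 ± 0.60 (adjusted p = 1.08e-07), and AZI1 at least 219-fold (adjusted p = 1.03e-10). The beta-amylase gene BAM5 fell by 5.34 ± 1.04 (adjusted p = 0.000533), NIG1 fell by 4.16 ± 0.62 (adjusted p = 2.81e-05), and 2A6 fell at least 8.29-fold to below background (adjusted p = 1.03e-10). Groups did not overlap for any of them. FT passed upward (adjusted p = 0.00265), but its rise has no certain size, since it was well above background in 1 of 6 arrays at 20 °C. The same held for WNK9, also in 1 of 6. The count was 6343 genes, 3094 up and 3249 down, and 3381 without Col-0 replicate 1. No slide held arrays of both 20 °C and 1 or 3 weeks, so slide and cold cannot be told apart at these times. Cold-regulated genes (24 up, 1 down of 30, median 1.90, adjusted p = 8e-18), large-subunit (91 up, 1 down of 122, 99 and 1 adjusted over the list alone, median 1.09, adjusted p = 1.52e-21) and small-subunit ribosomal proteins (62 up, 1 down of 76, median 1.03, adjusted p = 3.26e-17) rose, the ribosomal lists with adjusted p = 0.306 and 0.367 with an estimated correlation. Biogenesis factors rose (11 of 39, median 0.30, adjusted p = 0.00266, and 0.471 with an estimated correlation), with a median of 0.59 with brightness as a covariate. Glucosinolate genes fell (15 of 16, median -1.34, adjusted p = 9.93e-10), with CYP79F2 at -2.57 ± 0.47 (adjusted p = 0.000296). This became adjusted p = 0.223 with an estimated correlation. Jasmonate genes fell (7 of 15, 8 adjusted over the list alone, median -1.01, adjusted p = 0.00055), with VSP2 at -3.69 ± 0.83 (adjusted p = 0.00202). The same members gave adjusted p = 0.306 with an estimated correlation. Salicylic acid defence genes rose (9 of 22, 10 adjusted over the list alone, median 1.45, adjusted p = 0.000658), with PR1 up by 5.37 ± 1.31 (adjusted p = 0.00375). The joint test of this list had adjusted p = 0.471 with an estimated correlation. For PR1 the groups overlapped and few arrays at 20 °C were well above background, so its size is uncertain. CBF genes (3 of 4, adjusted p = 0.00112) and clock genes (8 up, 1 down of 18, adjusted p = 0.00184) passed upward again, heat shock genes (1 up, 7 down of 13, adjusted p = 0.00179) downward, as did guard cell (3 of 8 down, adjusted p = 0.0288), trichome (3 of 3 down, adjusted p = 0.0304) and dividing-cell markers (4 of 13 down, adjusted p = 0.0334), and none of these passed with an estimated correlation.

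At 3 weeks in Col-0, the defence marker PR1 rose by 11.33 ± 1.31 (adjusted p = 5.02e-07), the late embryogenesis gene LEA7 by 8.69 ± 1.14 (adjusted p = 2.69e-06) and FMO1 by 8.27 ± 1.62 (adjusted p = 0.00028), and CYP71A13 at least 140-fold from below background (adjusted p = 1.35e-06). CYP78A8 fell by 7.17 ± 0.50 (adjusted p = 2.28e-10), MSRB6 fell by 4.88 ± 0.47 (adjusted p = 3.05e-08) and GSO1 fell at least 40.4-fold to below background (adjusted p = 2.24e-10). Groups did not overlap for any of them. The sizes for PR1, LEA7 and FMO1 are uncertain, as they were well above background in 2, 1 and 1 of 6 arrays at 20 °C, and CYP78A8 in 1 of 3 in the cold. In all 8691 genes were called, 4075 up and 4616 down. Without the filter on dim probes 12270 were called, 4077 up and 8193 down. Salicylic acid defence genes rose in 20 of 22 members (21 adjusted over the list alone, median 3.38, adjusted p = 4.12e-10, 0.422 with an estimated correlation). Senescence genes rose (7 of 8, median 3.72, adjusted p = 0.000111), with NAC6 up by 5.37 ± 0.45 (adjusted p = 5.45e-09). That list had adjusted p = 0.0787 with an estimated correlation. Cold-regulated genes (27 up, 1 down of 30, median 2.26, adjusted p = 2.5e-16), clock genes (9 of 18 up, 10 adjusted over the list alone, adjusted p = 0.00422), with LHY up by 3.58 ± 0.38 (adjusted p = 1.53e-07), CBF genes (3 of 4 up, adjusted p = 0.00518) and floral transition genes (8 up, 1 down of 14, median 1.10, adjusted p = 0.00518), with SPL5 up by 2.67 ± 0.25 (adjusted p = 2e-08), also passed. For clock, CBF and floral transition genes the adjusted p was 0.449, 0.422 and 0.422 with an estimated correlation. Dividing-cell markers fell (7 of 13, 8 adjusted over the list alone, median -1.15, adjusted p = 0.0173), with CYCD3;1 at -2.49 ± 0.35 (adjusted p = 7.38e-06), and glucosinolate genes fell (8 of 16, 9 adjusted over the list alone, median -0.69, adjusted p = 0.0188); the adjusted p was 0.71 for both with an estimated correlation. Ribosomal proteins no longer passed as lists (3 up, 18 down of 122 in the large subunit and 6 down of 76 in the small), nor did biogenesis factors (2 up, 4 down of 39) and anthocyanin genes (1 up, 7 down of 22, median -0.19, mean 0.12).

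The mutant was compared with its own 20 °C arrays to follow the same responses in the double mutant. At 24 hours LTI30 rose by 5.56 ± 0.43 (adjusted p = 3.14e-09), CIPK25 by 4.79 ± 0.32 (adjusted p = 5.06e-10) and RVE2 by 4.96 ± 0.37 (adjusted p = 2.38e-09), EXPA8 fell by 5.34 ± 0.53 (adjusted p = 1.06e-07) and SEN1 fell at least 111-fold to below background (adjusted p = 1.14e-08). CBF1 rose by 2.07 ± 0.48 (adjusted p = 0.00267) and CBF2 by 1.98 ± 0.45 (adjusted p = 0.00216). At 1 week COR27 rose by 7.06 ± 0.67 (adjusted p = 6.51e-08), AZI1 by 8.76 ± 0.55 (adjusted p = 2.17e-10) and PR1 by 5.45 ± 1.36 (adjusted p = 0.0036), and FT did not pass (adjusted p = 0.0974). At 3 weeks PR1 rose by 9.04 ± 1.36 (adjusted p = 1.71e-05) and LHY by 3.74 ± 0.39 (adjusted p = 1.4e-07), LEA7 and MYB90 rose at least 59.9-fold and 16.9-fold from below background (adjusted p = 2.9e-05 and 7.42e-06), and MSRB6 fell at least 1262-fold to below background (adjusted p = 2.92e-13). In each of these calls the cold arrays lay outside the range at 20 °C, where AZI1 was well above background in 1 and PR1 in 2 of 5 arrays.

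Counts in the mutant were 4585, 6129 and 6378 genes at 24 hours, 1 week and 3 weeks, and 4085 at 3 weeks without mutant replicate 1 at that time. With slide as a block the 24-hour count was 3363. Biogenesis factors rose in 30 of 39 members at 24 hours (32 adjusted over the list alone, median 1.24, adjusted p = 3.34e-19), 27 at 1 week (31, median 1.26, adjusted p = 2.93e-15) and 7 at 3 weeks (6, median 0.43, adjusted p = 0.000461); at 24 hours the adjusted p was 0.0646 with an estimated correlation and at 1 week 0.109. Ribosomal protein genes rose in 41 of 122 large-subunit and 25 of 76 small-subunit members at 24 hours (52 and 27 adjusted over the list alone, medians 0.64 and 0.69), and in 104 and 65 at 1 week (112 and 73, medians 1.21 and 1.199, adjusted p = 4.26e-27 and 3.22e-23). For both lists the adjusted p was 0.429 at 24 hours and 0.328 at 1 week with an estimated correlation. At 3 weeks neither list passed and the small-subunit median changed sign with the scaling. Cold-regulated genes rose in 18 of 30 at 24 hours and at 1 week and in 19 at 3 weeks, with 1 lower (median 1.35, 1.40 and 1.56, adjusted p = 2.56e-13, 2.42e-11 and 8.19e-11), and adjusted p = 0.0644, 0.0641 and 0.131 with an estimated correlation. Photosynthesis genes fell in 11, 7 and 18 of 22 members (adjusted p = 2.28e-05, 0.00165 and 4.48e-07), the last with a median of -1.22 and adjusted p = 0.455 with an estimated correlation. That median was -0.25 under quantile normalization and under normexp. Anthocyanin genes rose in 13, 10 and 14 of 22 members (adjusted p = 6.17e-08, 0.000306 and 0.00126), glucosinolate genes fell in 13 of 16 at 1 week and at 3 weeks (adjusted p = 1.49e-05 and 3.53e-07), and salicylic acid defence genes rose in 15 of 22 at 3 weeks (median 1.86, adjusted p = 3.87e-07). None of the mutant's list calls held with an estimated correlation. The cold responses of the genotypes shared 3354, 3791 and 4358 calls of the same sign at the 3 times, with 10, 14 and 47 of opposite sign. Across genes, which are not independent, they correlated at r = 0.650 ± 0.2, 0.774 ± 0.133 and 0.758 ± 0.145 (jackknife SE). The slopes of the mutant on Col-0 were 0.476 ± 0.224, 0.780 ± 0.259 and 0.662 ± 0.273, so at 1 week and 3 weeks they lay within 2 SE of 1. The Col-0 response at 24 hours held both dim arrays. Noise in the Col-0 values also lowers such slopes, so a slope below 1 does not by itself show a weaker response in the mutant.

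Whether the genotypes differed in their cold response was tested directly as an interaction. Its 3-week values also span the difference in rosette stage between the genotypes. At 3 weeks the sulphur deficiency gene ATSDI1 rose by 2.06 in Col-0 and 6.12 in the mutant, an interaction of 4.05 ± 0.45 (adjusted p = 5.98e-05), and RL6 changed by -0.21 and -6.19 (interaction -5.98 ± 0.81, adjusted p = 0.000267). PDF1.2 rose by 3.39 in Col-0 and fell by 3.08 in the mutant (interaction -6.47 ± 1.19, adjusted p = 0.00583). REIL2 differed by -0.27 in Col-0 and 2.49 in the mutant (interaction 2.76 ± 0.51, adjusted p = 0.00612). At 24 hours TRFL8 fell by 2.15 in Col-0, with 0.52 in the mutant (interaction 2.68 ± 0.36, adjusted p = 0.00282). It was well above background in 2 of 3 Col-0 arrays at 24 hours, and that group held both dim arrays. The interaction passed for 4 genes at 24 hours, 101 at 1 week and 262 at 3 weeks (1 up and 3 down, 50 and 51, 101 and 161), and for 2, 29 and 129 with slide as a block. The share of 1-week calls that were upward, 49.5%, was 72.4% with slide as a block, 66.7% with only the 20 °C arrays on slides shared with 24 hours, 61.1% under normexp, 36.3% when only the groups compared were fitted, and 90.9% without mutant replicate 3 at 1 week. At 24 hours the count was 8649 without Col-0 replicate 1 at that time, 11 without Col-0 replicate 2 at 20 °C, 8 without mutant replicate 1 at 20 °C and 2 without Col-0 replicate 3 at 20 °C. It was 1 without any other array except Col-0 replicate 6 at 20 °C. At 1 week it was 59 and 58 without Col-0 replicates 3 and 5 at 20 °C, and 47, 66, 60 and 56 without mutant replicates 2 to 5 at 20 °C. It was 26, 43 and 203 without Col-0 replicates 1 to 3 and 53, 50 and 11 without mutant replicates 1 to 3 at 1 week. At 3 weeks it was 87 without Col-0 replicate 3 and 123 without mutant replicate 3 at that time, and 158 without mutant replicate 2 at 20 °C. The upward share at 3 weeks, 38.5%, was 50.6% without Col-0 replicate 3 and 24.3% without mutant replicate 2 at that time.

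As lists, biogenesis factors had a positive interaction at 1 week in 38 of 39 members (1 called, 12 adjusted over the list alone, median 0.79, adjusted p = 2.01e-17) and at 3 weeks in 37 (0 called by limma, median 0.68, adjusted p = 3.79e-07), with adjusted p = 0.133 and 0.352 with an estimated correlation. Brightness as a covariate gave medians of 0.63 and 0.28. Cold-regulated genes had a negative one at 24 hours (median -1.30, adjusted p = 3.47e-08, 0 called, 17 adjusted over the list alone), at 1 week (median -0.70, adjusted p = 7.06e-05) and at 3 weeks (median -0.75, adjusted p = 1.82e-05, 2 called, 4 adjusted over the list alone). With an estimated correlation the adjusted p was 0.393 at 24 hours, 0.399 at 1 week and 0.306 at 3 weeks. The 24-hour median was -0.73 under quantile normalization, -0.80 without both dim arrays and -0.55 with brightness as a covariate. At 1 week these medians were -0.46 under quantile normalization and -0.41 with the covariate, and at 3 weeks -0.55 under quantile normalization and -0.39 under normexp. Anthocyanin genes had a positive one at 3 weeks in 21 of 22 members (4 called, 7 adjusted over the list alone, median 1.39, adjusted p = 4.2e-08, 0.27 with an estimated correlation). Large-subunit and small-subunit ribosomal proteins had negative ones at 24 hours (medians -0.85 and -0.80, adjusted p = 1.16e-11 and 5.68e-11, 1 and 0 called), with adjusted p = 0.695 for both with an estimated correlation. With brightness as a covariate the medians were 0.02 and 0.05, and the small-subunit test reversed (adjusted p = 0.833). Without both dim arrays they were -0.05 and 0.03. No interaction call of a list held with an estimated correlation.

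The genotype effect at 20 °C was also set beside the Col-0 cold response, to see whether warm-grown mutants resembled cold-treated Col-0. Across genes, which are not independent replicates, r was 0.208, 0.196 and 0.192 at 24 hours, 1 week and 3 weeks. Both comparisons used the Col-0 arrays at 20 °C. A simulation of noise alone in every group, with the controls shared and no cold response, gave 0.389, 0.388 and 0.390. A real cold response adds spread and lowers r, so the simulated r cannot be set against the real one. Such a response adds nothing to the covariance that shared controls alone would give. The covariance was 0.0893, 0.0706 and 0.0907, against 0.0453, 0.0453 and 0.0455 in the simulation. With the Col-0 arrays at 20 °C split between the comparisons, r averaged 0.118, 0.093 and 0.111 and ranged below 0 at 1 week and 3 weeks.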

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

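The array values below were set apart because they lay far from the other arrays of their group. Only the groups at 20 °C were screened in this way, so the cold arrays, the dim ones included, were not. Of 86 values tested in this way 11 were set apart, where 4.3 would be by chance, since about 1 in 20 groups is set apart by chance alone. Among Col-0 arrays at 20 °C replicate 2 differed in 7 values. Its median for large-subunit ribosomal proteins was 0.565 (others -0.168 to -0.057) and for the small subunit 0.520 (others -0.15 to -0.037). Clock genes had -0.285 (others 0.045 to 0.153), starch and sugar genes -0.761 (others -0.085 to 0.318) and dividing-cell markers 1.033 (others -0.451 to -0.052). Its REIL2 level was 1.193 (others 0.307 to 0.546) and its COW1 level -3.333 (others -4.057 to -3.973). Among mutant arrays at 20 °C replicate 1 had medians of -0.536 for large-subunit (others 0.13 to 0.366), -0.532 for small-subunit (others 0.057 to 0.289) and -0.454 for organellar ribosomal proteins (others -0.006 to 0.154), and a COW1 level of -7.751 (others -6.262 to -5.925). Both arrays were kept, and leaving out either did not remove the COW1 call at 20 °C.

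Interactions were set apart because they test whether the genotypes differed in their cold response, with 4, 101 and 262 genes called. At 24 hours TRFL8 had an interaction of 2.675 and RPL3B of -1.387, since RPL3B rose by 1.395 in Col-0 and stood at 0.008 in the mutant. RPL3B kept its call in 5 of 17 leave-outs, with an adjusted p of 0.142 without mutant replicate 1 at 24 hours.

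At 1 week NUDT24 (4.254), AAE12 (3.793), SAG29 (3.787), NDB4 (3.538), FT (-6.261), GASA6 (-4.716), EXPA8 (-3.695) and MSRB6 (-3.114) had the largest fitted values with a symbol. None kept its call in every leave-out. NUDT24 kept it in 14 of 17, with an adjusted p of 0.0755 without Col-0 replicate 1, 0.0638 without mutant replicate 2 and 0.086 without mutant replicate 3 at 1 week. EXPA8 also kept it in 14, GASA6 in 13, AAE12 in 8, FT and MSRB6 in 7, and NDB4 and SAG29 in 1. NUDT24 was not well above background in Col-0 at 1 week or in the mutant at 20 °C, nor FT in the mutant at 1 week, nor NDB4 in any of the groups but the mutant at 1 week, so these fitted values are no bounds and their order by size is not known. AAE12 was well above background in 1 of 3 Col-0 arrays at 1 week.

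At 3 weeks those with the largest fitted values were NUDT24 (5.975), ATSDI1 (4.052), NIG1 (3.836), MYB11 (3.305), PDF1.2 (-6.473), PDF1.2b (-6.246), RL6 (-5.983) and MSRB6 (-5.871). All but NIG1 kept their call in every leave-out. NIG1 lost it without mutant replicate 2 at 20 °C (adjusted p = 0.056), Col-0 replicate 3 (0.157), mutant replicate 2 (0.0643) or mutant replicate 3 (0.0809) at 3 weeks. NUDT24 was not well above background in the mutant at 20 °C, nor MYB11 in Col-0 at 3 weeks, nor MSRB6 in the mutant at 3 weeks, so their fitted values are no bounds and their order by size is not known.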

How the results depend on the processing

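Most alternatives were fixed in advance; the brightness covariate, the fits without both dim arrays or with 1 mutant array, the blocked lists and the kept RPP loci were chosen after seeing the data. The cause of a change was not tested unless stated. Leaving out arrays was run for counts and named genes, not for gene lists. Signal over background limits what can be said of genes near background, and labels do not show separate plants. Where 1 array stood for a group it was assumed to vary like the other groups.

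Counts are given by setting. Deposited values gave 56 genes between genotypes at 20 °C, 383 at 24 hours and 753 at 1 week, 6718 and 3686 for Col-0 at 24 hours and 1 week, and 9 for the 24-hour interaction. These fits left out the 6 arrays at 20 °C on slides without cold arrays. Scanner values of the same remaining arrays gave 32 genes between genotypes at 20 °C, so the count of 56 also reflects fewer arrays. Fits of only the groups compared gave 410, 46, 143 and 236 between genotypes in order of time, 8933 for the mutant at 24 hours, and 577 and 190 for the interactions at 24 hours and 1 week. With only the 20 °C arrays on slides shared with 24 hours, genotype at 20 °C gave 32, Col-0 at 1 week 3389, the mutant 2739, 3616 and 3877, and the interactions 7, 63 and 111. With the other 20 °C arrays Col-0 at 1 week gave 3885 and the interactions 15, 22 and 99. Brightness as a covariate gave 351, 188 and 2086 between genotypes at 20 °C, 24 hours and 1 week, 7583 and 9717 for the mutant at 24 hours and 1 week, and 2 and 270 for the first interactions. Quantile normalization gave 1641 at 24 hours between genotypes and normexp 1699, with 38 for the 24-hour interaction; normexp moved the upward share of the 1-week interaction from 49.5% to 61.1%. Without a filter the genotype count at 24 hours was 1217, the mutant at 3 weeks 9895, and the interactions at 24 hours and 1 week 1 and 48. Slide as a fixed block gave 975 and 752 between genotypes at 24 hours and 1 week, and 2, 29 and 129 for the interactions. Slide as a random block (correlation -0.025) and the mean over probes each gave 2 for the 24-hour interaction. The replicate block gave 152, 556, 749 and 1038 between genotypes and 2, 48 and 136 for the interactions; only at 1 week did every pair of equal numbers correlate above 0.1. A 2-fold threshold gave 1830 at 24 hours between genotypes, 6361, 3576 and 5233 in Col-0, and 2609, 3634 and 3961 in the mutant. Without both dim arrays the genotypes at 24 hours gave 40, Col-0 3047 and the interaction 0. With only array 1, 2 or 3 of the mutant at 24 hours the genotype count was 29, 60 and 52, the mutant's cold count 1177, 1240 and 1355, and the interaction 1, 2 and 0.

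Leaving out 1 array gave 97 to 172, 190 to 11058, 510 to 1373 and 651 to 2295 genes between genotypes at the 4 times. It gave 6528 to 12417, 3381 to 7841 and 5961 to 9433 in Col-0, and 3079 to 4127, 4290 to 5552 and 4085 to 6539 in the mutant. The interactions ranged from 1 to 8649, 11 to 203 and 87 to 389.

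Of 154 list calls 3 held with an estimated correlation, 131 under quantile normalization, 150 with slide as a random block, 151 with the replicate block and 146 without a filter. With the brightness covariate 110 held, 34 were weaker and 10 changed direction. With the covariate these lists changed direction at 24 hours between genotypes: cytosolic ribosomal proteins of the small subunit (adjusted p = 0.933), plastid and mitochondrial ribosomal proteins (0.933), photosynthesis (0.122) and dividing cells (0.406). In the 24-hour interaction the same lists did so, with 0.833, 0.301, 0.301 and 0.314, and plastid and mitochondrial ribosomal proteins also in the interactions at 1 week (0.715) and 3 weeks (0.286). The genes rps15ae, PSRP5 and MCM5 moved to 0.02, 0.053 and -0.04 at 24 hours. Of 415 calls and values of named genes 55 were weaker with the covariate, 67 with the replicate block, 26 under quantile normalization, 34 under normexp and 14 with slide as a random block, and 54 of 94 without both dim arrays. Leaving out 1 array weakened 450 of 3509. Under quantile normalization photosynthesis changed direction at 24 hours between genotypes (0.254) and in the interaction (0.288). Without both dim arrays small-subunit ribosomal proteins (0.74) and photosynthesis (0.999) did so between genotypes, and plastid and mitochondrial ribosomal proteins in the cold response of Col-0 (0.765) and in the interaction (0.949). With the 20 °C controls split, likeness to cold at 1 week averaged 0.093.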

Other observations

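In the 24-hour genotype comparison organellar ribosomal proteins had 9 of 21 members called lower (median -0.94, adjusted p = 0.000127) and small-subunit cytosolic ones 6 of 76 (median -0.75, adjusted p = 7.07e-10), and both lost their direction with brightness as a covariate. Neither held with an estimated correlation (adjusted p = 0.657 for both), and the medians were -0.03 and 0.07 without both dim arrays. In the mutant's own 24-hour response biogenesis factors rose in 30 of 39 members (median 1.24, adjusted p = 3.34e-19) and rRNA processing genes in 6 of 12, with 1 lower (adjusted p = 0.000564). These became adjusted p = 0.0646 and 0.429 with an estimated correlation.

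The tests of the dim arrays by correlation, of mixed material and of probe sequences were chosen after seeing the result. Many more genes were called between the genotypes at 24 hours (2783) than at 20 °C (180). Scaling may account for a part, as quantile normalization gave 1641, and the dim Col-0 arrays for a large part. The dim-minus-bright difference correlated at r = 0.876 with the slope towards dim arrays at 1 and 3 weeks (0.084 with that at 20 °C). With the former slope the genotype effect had r = -0.772 at 24 hours and 0.038 at 20 °C. The count without both dim arrays met the limit set but lay among those with 1 mutant array. It cannot part dimness from the smaller group. A genotype difference arising in the cold stays open. The interaction from slides 1 and 7 correlated with that from slides 2, 3, 8 and 9 at r = -0.04 across genes. The latter held both dim arrays, so brightness parts them and the limit set decides nothing.

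REIL2 signal in the mutant rose at 3 weeks by 2.49 ± 0.37 (adjusted p = 1.45e-05). Col-0 material mixed into the mutant samples was argued against, since REIL1 should then have risen too and differed by -1.007. The scaling was argued against, with a larger adjusted p of 4.75e-05 under the other scalings. Transcription across the insertion or from a partly restored locus might contribute and stays open, and was not tested.

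Of the genes that differed in the same direction at all 4 times, 54 remained without the mutated loci. Stretches of chromosome next to the mutated loci were argued against as the main source: 5 of 54 lay within 500 loci of either gene, against 1244 of 20295 others (Fisher's exact p = 0.384, odds ratio 1.56). Sequence differences under the probes would be likely to lower signals, and 36 were higher against 18 lower (binomial p = 0.0198, with genes taken as independent). All of these genes are among the 20 °C calls, of which 126 of 180 were higher in the mutant. The binomial test against equal shares therefore cannot weigh this explanation. A higher signal argues against sequence differences for the 36 higher genes only, and for the 18 lower ones they stay open. A lasting effect of the mutations or of the background stays open.

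Random splits of the arrays were used to ask whether chance could give counts as large. For genotype at 20 °C chance was argued against (180 genes, highest other split 70, with 1 of 100 as large, itself). The same held for Col-0 at 24 hours (10117, highest other 8914), 1 week (6343, highest other 1698) and 3 weeks (8691, highest other 1758), each 1 of 84. It also held for the mutant (4585, 6129 and 6378, highest others 139, 143 and 996), each 1 of 56. No allowance was made for the number of comparisons. If arrays of a group shared plants, such splits cannot speak to chance differences between plants. The split with 8914 set Col-0 replicates 2 and 3 at 24 hours and replicate 2 at 20 °C apart. With 3 arrays against 3 there are too few splits (10) for a share under 0.05: at 24 hours the real count was 2783 and the highest other 30, and at 3 weeks 1560 and 5. At 1 week a split of Col-0 replicates 1 and 2 and mutant replicate 1 from the rest gave 2484 against 1143. So 2 of 10 were as large. The arrays so set apart were the dimmest at 1 week. Their log2 75th percentiles were 9.41, 10.17 and 9.99, against 10.45 for Col-0 replicate 3 and 10.80 and 10.66 for mutant replicates 2 and 3. That split thus also follows brightness. Col-0 and mutant replicate 1 share a slide as well, and the slide-blocked count was 752. For the interactions 21, 21 and 20 of 100 splits were as large as the real 4, 101 and 262, with highest others of 679, 730 and 988. Of the 99 others 21 kept the genotypes apart in the cold and so held the genotype difference there, and 19, 20 and 19 of these were as large. They are no measure of chance, and the structure behind the highest counts is the genotype grouping in the cold. Of the 78 that mixed the cold arrays 1, 0 and 0 were as large (highest 150, 0 and 4), a count made after seeing the result. The 6 cold arrays of a time allow 10 groupings, too few to settle whether chance is excluded.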
